A study of Mus musculus with 28 samples.

How the data were processed

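Small RNA was sequenced from 28 left ventricular samples of neonatal and juvenile Hsd:ICR(CD-1) mice, an outbred stock. The labels give 8 groups, formed by operation (sham or myocardial infarction, MI), operation day (postnatal day 1, P1, or 7, P7) and follow-up (3 or 21 days). Each library is named here by its group and replicate number. The labels do not state outright that each library comes from a different mouse, and p-values measure the spread between these samples.

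Per the labels' protocols, ventricular tissue from the remote zone was frozen, RNA was isolated with TRIzol, and 100 ng of total RNA entered each library. The 3-day libraries were made with the Qiagen QIAseq miRNA kit and sequenced on a NextSeq500, and the 21-day libraries were made with the Illumina TruSeq Small RNA kit and sequenced on a HiSeq2000, per the labels' protocols. Follow-up and kit cannot be told apart, so libraries of the 3-day and 21-day follow-ups were never fitted together and their levels are not compared. The submitters' processing notes name Bowtie2 2.2.2, edgeR (with no version) and the GRCm38 genome build, without their role or order. The counter, the miRNA annotation, adapter trimming and any use of molecular identifiers are not given in the sources used here.

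The authors deposited whole-number counts per library, listed per pair of hairpin and mature miRNA, with no normalization and with 1 as the lowest listed value. These counts covered 1614 pairs of hairpin and mature miRNA and 1485 mature names. Of the 70 mature names listed under several hairpins, 35 held over 1000 reads, and for 30 of these the counts under the different hairpins lay within 10% of each other. The same reads may thus have been counted under each hairpin, which was not tested. One value per mature miRNA was therefore kept, the highest over its hairpins. Reads may likewise have been counted under near-identical names: 12 pairs of names with at least 50 reads had counts within 5% of each other, among them miR-199a-3p with miR-199b-3p and miR-486a-5p with miR-486b-5p, and values of these are uncertain as to which gene made the RNA.

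Deposited counts summed to 1.29 to 13.0 M per library at 3 days and to 18.2 to 26.9 M at 21 days; after collapsing, the totals were 0.858 to 8.90 M and 14.9 to 21.5 M. Counts above 0 were seen for 621 to 1023 and 909 to 1028 mature names per library. No libraries looked like copies of each other: the lowest chi-square per degree of freedom between replicates was 33.0, over miRNAs with at least 10 reads.

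Within each follow-up, edgeR 4.0.16 in R 4.3.3 was fitted to the 4 groups together with TMM normalization, filterByExpr at its defaults (minimum count 10) and the robust quasi-likelihood F test. Of all mature names, 446 were tested at 3 days and 598 at 21 days, with 12 and 8 residual degrees of freedom and a biological coefficient of variation of 0.545 and 0.250. Calls are at a Benjamini-Hochberg adjusted p under 0.05. CPM values are TMM-scaled counts per M counts (M, 1e6), the SE of a log2 fold change is its size divided by the square root of the F statistic, and all adjusted p-values of single miRNAs come from edgeR unless another tool is named. In each follow-up, 4 comparisons were made: MI against sham at P1, MI against sham at P7, the difference of these effects (P7 minus P1), and sham P7 against sham P1.

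The comparisons, the tests, the rule for named miRNAs, 18 lists of miRNAs and a set of processing alternatives were fixed before the data were examined. For each comparison the rule names the 12 highest and 12 lowest log2 fold changes among miRNAs past the threshold with a mean of at least 10 CPM. It adds the 6 smallest unadjusted p-values where fewer than 6 passed, the 5 miRNAs with the largest mean share per follow-up, and 2 to 4 members per list. The lists came from textbook knowledge: cardiac and striated muscle miRNAs, the miR-15, miR-17/92, miR-302/367, let-7, miR-29, miR-30 and miR-34 families, fibroblast-associated, mural, endothelial, immune and erythroid miRNAs, the Dlk1-Dio3 cluster, H19 and Igf2 hosted miRNAs, hypoxia-regulated miRNAs, hypertrophy and stress associated miRNAs, and markers of other tissues. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 60 list tests per follow-up. The camera test was repeated with an estimated correlation, with which 0 of the 60 list tests passed in either follow-up, and fry tested whether a list moved one way on balance, without comparing it with other miRNAs. The miR-302/367 cluster had 0 tested members, and the endothelial and hypoxia lists had 2 each, too few for a list test. The median, mean and camera direction of a list differed in sign in 19 of the 60 list tests at 3 days and 8 of the 60 at 21 days, and 0 of these passed.

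Alternatives were DESeq2 size factors, total count scaling, no filter, a filter of 10 CPM, the DESeq2 1.42.0 Wald test, limma-voom, fits of only the compared groups, leaving out each replicate, the title code as a random block at 3 days, and lane or a replicate block at 21 days. Total count scaling shifted log2 fold changes at 3 days by a median over miRNAs of 0.30 (MI at P1), 0.48 (MI at P7), 0.18 (difference) and -0.30 (sham age). At 21 days these median shifts were -0.19, 0.34, 0.53 and -0.22. With DESeq2 size factors the median shifts were 0.18, -0.14, -0.32 and 0.11 at 3 days, and less than 0.1 at 21 days. Changes are given relative to TMM.

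Shares of counts were compared with exact two-sided permutation tests. Correlations of log2 fold changes are across miRNAs, which are not independent replicates. Hairpins were matched by identifier to the GRCm38 annotation, which held 931 of 946, and GC content of the hairpin arm was available for 1333 mature names. The fits were tested on simulated data with the real means, library sizes and dispersions: edgeR recovered 26.8% and 81.2% of 2-fold and 4-fold changes for MI at P1 at 3 days, 21.3% and 75.3% for MI at P7, 3.26% and 29.6% for the difference, and 16.8% and 69.4% for sham age. At 21 days these shares were 65.3% and 95.9%, 60.4% and 96.0%, 33.7% and 79%, and 73.7% and 94%. Over both follow-ups 0.595% to 5.88% of simulated calls were false. In the first of these comparisons 97 and 96 of 429 miRNAs were changed 2-fold and 4-fold, about evenly up and down. Counts were drawn independently around a common mean per miRNA, with no split of the sham P1 libraries and no correlation within title codes. These shares therefore need not hold for the real libraries. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used for the remaining steps.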

Results

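The miRNAs of the left ventricle were sequenced in 28 libraries from Hsd:ICR(CD-1) mice after myocardial infarction (MI) or a sham operation. MI was made by ligating the left anterior descending coronary artery on postnatal day 1 (P1) or 7 (P7), and tissue of the remote zone, away from the infarct, was taken 3 or 21 days later at ages of 4, 10, 22 and 28 days. The mouse heart is known to regenerate muscle when injured just after birth and to lose this capacity within days, and the operation days lie on either side of that change. Each of the 4 groups held 4 libraries at 3 days and 3 libraries at 21 days. Deposited counts per library at 3 days were 1.56 to 9.26 M in sham P1, 5.61 to 13.0 M in MI P1, 1.61 to 3.42 M in sham P7 and 1.29 to 1.95 M in MI P7. At 21 days they were 22.8 to 26.9, 21.6 to 24.7, 18.8 to 26.7 and 18.2 to 24.3 M in the same order.

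Few miRNAs made up most of each library. At 3 days miR-125b-5p took a mean of 14.3% of counts, the striated muscle miRNA miR-133a-3p 13.7%, miR-125a-5p 8.04%, let-7b-5p 7.04% and let-7c-5p 5.47%. At 21 days, with another library kit, miR-22-3p took 13.3%, miR-133a-3p 10.6%, the smooth muscle miRNA miR-143-3p 6.64%, miR-378a-3p 6.10% and miR-486a-5p 5.20%. miR-486a-5p, with nearly the same counts as miR-486b-5p, is a member of the erythroid list, and the cells that made it were not tested.

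The sham P1 libraries at 3 days were of 2 kinds. The first principal component, with 72.1% of the variance, placed sham P1 replicates 1 and 2 (title code 1078) with all 4 MI P1 libraries, and replicates 3 and 4 (title code 1103) with all 8 P7 libraries. Among miRNAs chosen after their values were seen, miR-16-5p was at a mean of 92489 CPM in the code 1078 libraries and 2741 CPM in the code 1103 libraries, with 61745 CPM in MI P1 and 8664 CPM in sham P7. The endothelial miRNA miR-126a-3p was at 129646 and 4820 CPM, whereas miR-328-3p went the other way, with 258 and 4041 CPM. This split moves with every comparison below that uses the sham P1 libraries of 3 days. The liver marker miR-122-5p was at 1641 CPM in MI P1 replicate 1 and at 1.15 to 208 CPM in the other 3-day libraries.

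**Figure D1:**
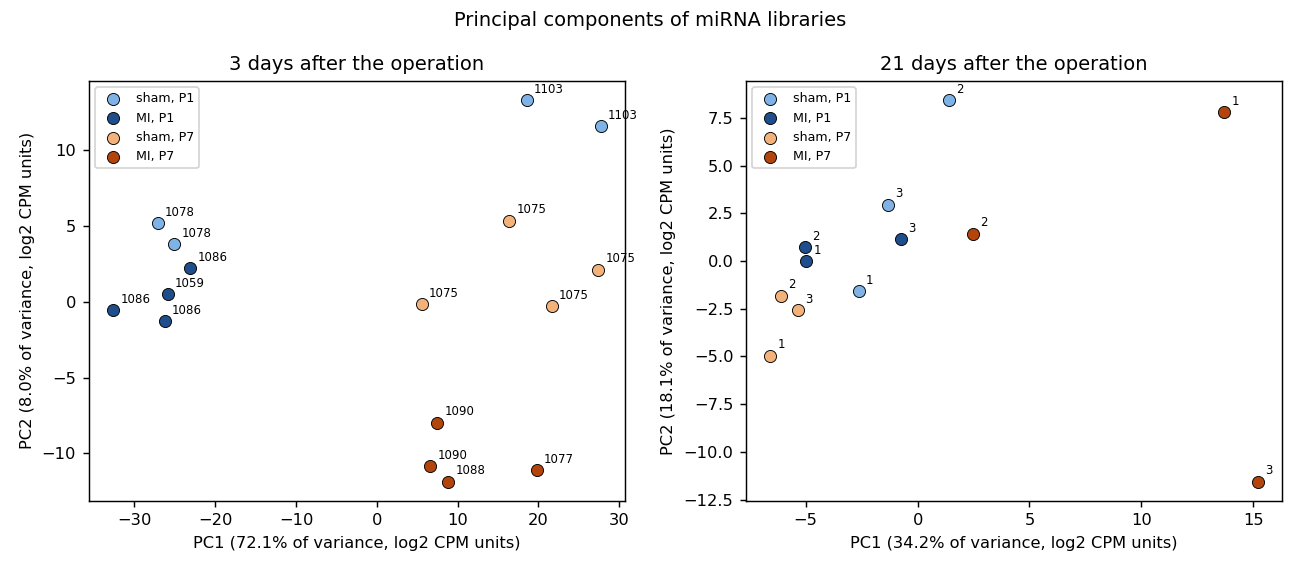
Principal components of the libraries of each follow-up from log2 CPM, with 1 point per library, coloured by group, and the title code beside each 3-day point. At 3 days the sham P1 libraries of code 1078 sit with MI P1 and those of code 1103 with the P7 libraries, along a component with 72.1% of the variance.

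At 3 days after MI at P1, 6 miRNAs were higher than in sham hearts and all 6 are named here. miR-146b-5p, which restrains inflammatory signalling, rose from 58.6 ± 60.5 to 332 ± 64.5 CPM (SD, n = 4 each), a log2 fold change of 2.48 ± 0.67 (SE, adjusted p = 0.0235). The haematopoietic miR-142a-3p rose by 2.71 ± 0.83 (adjusted p = 0.0345) and miR-206-3p, best known from skeletal muscle, by 2.21 ± 0.56 (adjusted p = 0.0230), from 17.5 ± 10.2 to 82.1 ± 52.5 CPM. The highest miR-206-3p value, 153 CPM, was in MI P1 replicate 1. MI P1 replicate 2 had 29.3 CPM, under the 30.2 CPM of sham P1 replicate 2. miR-206-3p is on the list of markers of other tissues, and whether admixed tissue raised it here or after MI at P7 was not tested. The p53-inducible miR-34c-5p rose by 1.49 ± 0.48, and miR-494-3p and miR-134-5p of the imprinted Dlk1-Dio3 cluster by 1.30 ± 0.40 and 1.17 ± 0.31. The larger number of miRNAs fell, led by miR-328-3p at -3.50 ± 0.82 (adjusted p = 0.0230), from 2149 ± 2227 to 190.1 ± 55.9 CPM, where the SD of the sham libraries exceeds their mean.

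In all, 82 of 446 tested miRNAs passed for MI at P1 at 3 days, 6 higher and 76 lower, and 9 higher and 23 lower with total count scaling. The named lower miRNAs were miR-328-3p, miR-1964-3p (-3.32), miR-326-3p (-2.97), miR-129-5p (-2.93), let-7d-3p (-2.91), miR-181a-5p (-2.87), miR-483-3p (-2.79), miR-504-5p (-2.72), miR-139-3p (-2.70), miR-3102-3p (-2.59), miR-193b-3p (-2.53) and miR-1249-3p (-2.49). These calls depend on the sham P1 libraries of code 1103 and on single libraries of both groups. Without the 2 libraries of code 1103, 0 miRNAs passed in edgeR, with 50 at an unadjusted p under 0.05. miR-146b-5p then had 1.55 (adjusted p = 0.0695), miR-206-3p 1.78, miR-142a-3p 1.82 and miR-328-3p -0.53. Leaving out 1 library gave 164 calls without sham P1 replicate 1, 162 without replicate 2, 1 without replicate 3. It gave 0 without sham P1 replicate 4 or MI P1 replicate 1, 2 or 4, so 0 of the 18 named calls held in every such fit. DESeq2 called 122, limma-voom 11, and 0 passed with only the 2 groups in the edgeR fit (120 at an unadjusted p under 0.05) or in limma-voom with the title code as a random block (49).

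A set of 4 lists lay higher than other miRNAs after MI at P1 at 3 days with the preset correlation. The fibroblast-associated list had adjusted p = 0.0058, and adjusted p = 0.44 with an estimated correlation. Of its 7 members 0 passed and 3 were higher adjusted over the list alone, and miR-21a-5p had 2.49 ± 0.90 and miR-199a-5p 1.03 ± 0.39. Of 9 immune cell miRNAs, 2 rose (miR-142a-3p and miR-146b-5p) and the lymphocyte miRNA miR-150-5p fell (-1.89), against 4 and 1 adjusted over the list alone, with a list adjusted p = 0.0127 (adjusted p = 0.55 with an estimated correlation). The Dlk1-Dio3 list of 43 tested members had 2 higher and 2 lower (miR-370-3p -1.97 and miR-668-3p -1.94), 0 adjusted over the list alone, and adjusted p = 8.0e-04 (adjusted p = 0.44 with an estimated correlation). The hypertrophy and stress list, with 0 of 9 past either adjustment, had adjusted p = 0.0138 (adjusted p = 0.63 with an estimated correlation), and 0.0714 without sham P1 replicate 1. Without the code 1103 libraries these 4 list tests still passed, at adjusted p = 0.0019, 0.0040, 4.3e-09 and 0.0189, with 0 members past in any of them. The median log2 fold change was then 0.42 in place of 1.03 for the fibroblast-associated list and 0.87 in place of 1.88 for the immune list.

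Members of other lists fell after MI at P1 at 3 days with no list test passing. They were miR-133a-3p (-1.48 ± 0.43, adjusted p = 0.0283) as 1 of 7 cardiac miRNAs, miR-15b-5p (-1.13) as 1 of 6 of the miR-15 family, miR-92a-3p (-1.84) as 1 of 9 of miR-17/92, let-7b-5p (-1.32) as 1 of 10 of let-7. Also lower were miR-486a-5p and its near copy miR-486b-5p (-2.47) as 2 of 5 erythroid miRNAs, and miR-483-3p and miR-483-5p (-2.30) as 2 of 3 H19 and Igf2 hosted miRNAs. miR-34c-5p was the 1 of 3 miR-34 members that rose, and of 7 other-tissue miRNAs miR-206-3p rose and the epithelial miR-200c-3p fell (-1.93). Adjusted over the list alone the counts were equal but for 2 higher in the miR-34 family and 2 lower among other-tissue miRNAs. None of the miR-29, miR-30, mural, endothelial or hypoxia members passed. The median, mean and test of the cardiac, miR-17/92, erythroid and other-tissue lists differed in sign.

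At 3 days after MI at P7, 23 miRNAs rose and 2 fell, though the share that fell depends on the method: it was 23 against 29 higher in DESeq2. miR-21a-3p, from the injury-responsive miR-21 hairpin (GRCm38 chromosome 11, 86584067 to 86584158, minus strand, in an exon of Vmp1), went from 10.8 ± 5.89 to 212 ± 63.0 CPM (SD, n = 4 each), a log2 fold change of 4.34 ± 0.59 (SE, adjusted p = 3.1e-04). miR-206-3p (chromosome 1, 20679010 to 20679082, in an intron of the lincRNA Gm28653) rose from 2.23 ± 1.37 to 29.7 ± 12.3 CPM (3.66 ± 0.69, adjusted p = 0.0047), and miR-31-5p from 72.0 ± 16.3 to 254.5 ± 34.3 CPM. The antifibrotic miR-29a-3p (chromosome 6, 31062660 to 31062747) rose from 582 ± 288 to 1885 ± 170.3 CPM (1.69 ± 0.34, adjusted p = 0.0078). Of 43 Dlk1-Dio3 miRNAs 10 rose (list adjusted p = 1.2e-11; adjusted p = 0.056 with an estimated correlation), among them miR-134-5p from 131 ± 30.2 to 578 ± 45.5 CPM and miR-409-3p from 188 ± 40.6 to 788 ± 43.0 CPM.

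For MI at P7 at 3 days, 25 of 446 miRNAs passed, 23 higher and 2 lower. The named ones after miR-21a-3p and miR-206-3p were miR-146b-5p (2.78 ± 0.70), miR-214-5p (2.57 ± 0.56), miR-540-3p (2.53 ± 0.40), miR-134-5p (2.14 ± 0.32), miR-409-3p (2.07 ± 0.27), miR-494-3p (2.01), miR-34c-5p (1.95), miR-31-5p (1.82), miR-29a-3p (1.69) and miR-300-3p (1.57). The 2 that fell were miR-107-3p (-1.32, from 866 ± 104 to 347 ± 96.5 CPM) and miR-181c-3p (-1.01). All 25 calls were kept without the code 1103 libraries, when 93 passed (62 higher and 31 lower). Those libraries are not in this comparison and enter only through the pooled spread, the filter and the scaling, so this does not test the calls. Leaving out 1 library gave 13 to 23 calls. There were 13 without sham P7 replicate 2, MI P7 replicate 2 or MI P7 replicate 4, 14 without sham P7 replicate 3, and 15 without sham P7 replicate 4 or MI P7 replicate 1. Of the 14 named calls 9 held in every such fit, while miR-146b-5p, miR-34c-5p, miR-300-3p, miR-107-3p and miR-181c-3p missed the threshold without most single libraries, with adjusted p up to 0.150. Total count scaling gave 58 calls, all higher, and only the 2 groups in the fit 65 (43 higher and 22 lower), against 8 with no filter and 0 in limma-voom with the title code as a random block (12 at an unadjusted p under 0.05; 26 in limma-voom without the block, 52 in DESeq2, 29 higher and 23 lower).

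Of 43 tested Dlk1-Dio3 members, whose 40 hairpins span chromosome 12 from 109585789 to 109743795, 10 rose and 0 fell after MI at P7 at 3 days (adjusted p = 0.056 with an estimated correlation), and 16 were higher adjusted over the list alone. The 10 became 5 with DESeq2 size factors and 22 with total count scaling. They became 4 without MI P1 replicate 1, 3 or 4, sham P7 replicate 3 or MI P7 replicate 2 or 4, 5 without sham P7 replicate 2, and 6 without sham P1 replicate 4, sham P7 replicate 4 or MI P7 replicate 1 or 3. Of 7 fibroblast-associated miRNAs 2 rose (miR-21a-3p and miR-214-5p), and 5 adjusted over the list alone, with adjusted p = 2.6e-05 (adjusted p = 0.175 with an estimated correlation). Of 9 hypertrophy and stress miRNAs 2 rose, miR-222-3p (1.40) and miR-212-3p (2.52), and 6 adjusted over the list alone, with adjusted p = 0.0011 (adjusted p = 0.55 with an estimated correlation). With total count scaling 4 fibroblast-associated and 6 hypertrophy and stress members were higher. Without the code 1103 libraries 6 of each of these 2 lists were higher and 4 let-7 members lower. Leaving out 1 library gave 2 to 3 fibroblast-associated and 1 to 3 hypertrophy and stress members. The let-7 list, whose members mark mature tissue, lay lower at adjusted p = 0.0264 (adjusted p = 0.67 with an estimated correlation) with 0 of 10 past and 3 lower adjusted over the list alone. It did not pass without MI P7 replicate 1 or 2 (adjusted p up to 0.0824), and let-7b-5p had -1.11 ± 0.40 and let-7c-5p -1.09 ± 0.33. Single members rose in lists whose test did not pass: 1 of 3 miR-29, 1 of 3 miR-34, 1 of 9 immune and 1 of 7 other-tissue miRNAs, and the hypoxia-induced miR-210-3p from 249 ± 70.9 to 569 ± 98.7 CPM (1.19). Adjusted over the list alone these were 1, 2, 3, 1 and 1, with 1 of 3 H19 and Igf2 hosted miRNAs lower. None of the cardiac, miR-15, miR-17/92, miR-30, mural, endothelial or erythroid members passed either adjustment. Sign differed between median, mean and test for the miR-15, mural, erythroid and other-tissue lists.

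**Figure D2:**
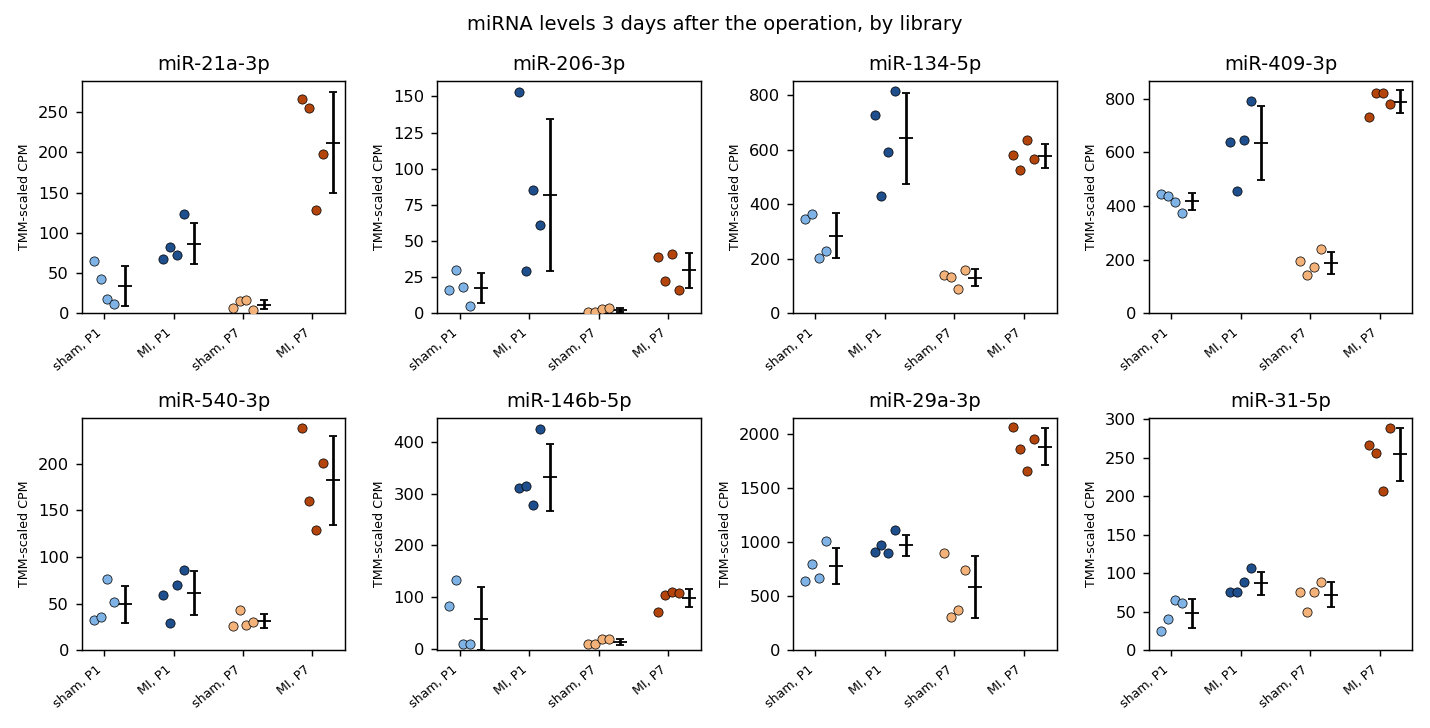
TMM-scaled CPM of single miRNAs in the 3-day libraries, with 1 point per library and bars for the mean and SD of each group (n = 4). miR-21a-3p was at 212 ± 63.0 CPM in MI P7 and 10.8 ± 5.89 CPM in sham P7.

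The difference of the MI effects at 3 days was not resolved for any single miRNA. In edgeR 0 of 446 passed, with 71 at an unadjusted p under 0.05 and a smallest adjusted p of 0.132, and DESeq2 called 6 and limma-voom 0. The 6 with the smallest p, none of which passed, were miR-540-3p (2.21 ± 0.55), miR-21a-3p (3.02 ± 0.74), miR-195a-3p (1.69 ± 0.42), miR-409-3p (1.47 ± 0.38), miR-218-2-3p (4.71 ± 1.25) and miR-326-3p (3.16 ± 0.97). On simulated data this comparison recovered 29.6% of 4-fold changes. Without the code 1103 libraries 1 miRNA passed, miR-21a-3p, at 3.74 (adjusted p = 7.5e-04). The let-7 list (adjusted p = 0.0044; adjusted p = 0.58 with an estimated correlation) and the miR-30 list (adjusted p = 0.0268; adjusted p = 0.55 with an estimated correlation) lay lower, with 0 of 10 and 0 of 5 members past either adjustment, let-7c-5p at -0.81 ± 0.46 and miR-30c-5p at -1.02 ± 0.80. No member of any other list passed, and adjusted over the list alone 1 each of the miR-15, miR-29 and fibroblast-associated lists and 2 Dlk1-Dio3 members were higher. For the mural, immune, erythroid and other-tissue lists the median, mean and test were not of 1 sign. Neither list test passed without the code 1103 libraries (adjusted p = 0.402 and 0.219).

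Between sham hearts of 4 and 10 days of age, the maturation-associated let-7b-5p rose from 44479 ± 23341 to 168212 ± 55820.2 CPM (n = 4 each), a log2 fold change of 1.92 ± 0.41 (SE, adjusted p = 0.0080). miR-34a-5p, which limits cell proliferation, rose from 1090.5 ± 412 to 3735 ± 1133 CPM (1.78 ± 0.36, adjusted p = 0.0080). miR-130b-3p fell from 179 ± 147 to 14.3 ± 12.9 CPM (-3.59 ± 0.76, adjusted p = 0.0080) and miR-708-5p from 54.7 ± 48.5 to 7.14 ± 1.42 CPM (-2.93 ± 0.61, adjusted p = 0.0080). These 4 were the only named calls of this comparison that held when any 1 of its libraries was left out. Leaving out 1 library keeps both title codes in sham P1, so it does not test their split. The mean of let-7b-5p was 25747 CPM in the code 1078 libraries and 63211 CPM in the code 1103 libraries. With the title code as a random block in limma-voom all 24 named calls were lost.

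For sham age at 3 days, 98 of 446 miRNAs passed, 17 higher and 81 lower, or 34 and 70 with DESeq2 size factors and 9 and 134 with total count scaling. The other named higher miRNAs were miR-185-3p (2.01), miR-671-3p (1.92), miR-874-5p (1.82), miR-486b-5p and miR-486a-5p (1.81 each), miR-139-5p (1.71), miR-1843a-3p (1.56), miR-342-5p (1.32), let-7c-5p (1.24) and miR-150-5p (1.23). The other named lower ones were miR-369-5p (-3.79), miR-301a-5p and let-7c-1-3p (-3.58 each), miR-322-3p (-3.43), miR-15b-3p (-3.23), miR-215-5p and miR-10b-5p (-2.96 each), miR-421-3p (-2.75), miR-98-5p (-2.72) and miR-379-5p (-2.70). With the code 1103 libraries as the only sham P1 libraries 73 miRNAs passed, of which 25 were among the 98. In that fit 5 of the 24 named kept their call, 12 lost it and 7 turned from lower to higher, miR-98-5p to 1.62 (adjusted p = 0.0228). With the code 1078 libraries alone 352 passed. Single libraries moved the count from 17 (without sham P7 replicate 2), 23 (sham P7 replicate 3), 26 (sham P1 replicate 2), 31 (sham P1 replicate 1) and 39 (sham P7 replicate 1) to 151 and 185 (sham P1 replicates 4 and 3). Fits of only the 2 groups gave 0 (48 at an unadjusted p under 0.05), the title code as a random block in limma-voom 0 (24), limma-voom 62 and DESeq2 147.

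The Dlk1-Dio3 cluster fell between the sham groups at 3 days in 22 of 43 members, and 23 adjusted over the list alone, with a list adjusted p = 6.3e-05 (adjusted p = 0.38 with an estimated correlation). The 22 became 7, 8 and 14 without sham P7 replicates 2, 3 and 1, and 11 and 12 without sham P1 replicates 2 and 1. Without the code 1103 libraries 8 of 44 members were higher and 26 lower, with list adjusted p = 0.0367. That fit keeps the code 1078 libraries as sham P1. The lists were not tested against the code 1103 libraries alone, so the split of the codes stays open for this fall. Against code 1103 alone the member miR-379-5p turned from lower to higher. miR-409-3p fell by 1.15 and miR-134-5p by 1.13 on the log2 scale. No other list test passed. The members that passed were 2 higher (let-7b-5p, let-7c-5p) and 1 lower (miR-98-5p) of 10 let-7, 3 lower of 9 miR-17/92 (miR-17-5p -2.17), 1 higher and 3 lower of 9 immune (miR-223-3p -2.66). There were also 2 higher of 5 erythroid, 1 higher and 1 lower of 9 hypertrophy and stress, and 1 higher of 3 miR-34. Another 1 each was lower of 7 cardiac (miR-133a-5p -1.66), 6 miR-15 (miR-16-5p -2.46), 5 miR-30, 7 fibroblast-associated (miR-21a-3p -1.73), 4 mural (miR-143-3p -1.88), 2 hypoxia (miR-210-3p -1.64) and 7 other-tissue miRNAs (miR-206-3p -2.91). Adjusted over the list alone the counts differed for let-7 (4 lower), miR-17/92 (4 lower), miR-15 (0), fibroblast-associated (2 lower) and mural (2 lower). None of the miR-29, endothelial or H19 and Igf2 hosted members passed. The fall of miR-16-5p rests on the code 1078 libraries. It was at 2609 to 2874 CPM in the code 1103 libraries, under the 5587 to 13693 CPM of sham P7. The median, mean and test of the cardiac, let-7, miR-34, immune, erythroid, hypertrophy and other-tissue lists differed in sign.

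At 21 days after MI at P1, both arms of miR-582 were lower than in sham hearts, and few other miRNAs moved. miR-582-3p (chromosome 13, 109324744 to 109324824, in an intron of the phosphodiesterase gene Pde4d) fell from 191 ± 78.2 to 25.3 ± 5.06 CPM (SD, n = 3 each), a log2 fold change of -2.92 ± 0.38 (SE, adjusted p = 0.0015). miR-582-5p fell from 31.4 ± 9.41 to 4.37 ± 0.379 CPM (-2.85 ± 0.40, adjusted p = 0.0015). The only other miRNA of 598 to pass, miR-184-3p (chromosome 9, 89802260 to 89802328), has a mean under 10 CPM and was named after its values were seen. It fell from 10.1 ± 3.07 to 2.10 ± 0.271 CPM (-2.26 ± 0.40, adjusted p = 0.014). Of the miRNAs with the next smallest p, none of which passed, miR-3108-5p had -1.69, miR-363-3p -1.19 and miR-130b-5p -0.71 (adjusted p = 0.383 each).

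The 3 calls at 21 days after MI at P1 were all lower, and 43 miRNAs had an unadjusted p under 0.05. Both arms held in every fit with 1 library left out, from -3.18 to -2.57 for miR-582-3p. With lane as a covariate both passed and miR-184-3p had -2.19 (adjusted p = 0.142), and with no filter 12 passed. With the preset correlation 4 list tests passed, with 0 of their members past either adjustment. The miR-30 list lay higher (adjusted p = 0.046; adjusted p = 0.65 with an estimated correlation) and so did the erythroid list (0.0164; adjusted p = 0.53 with an estimated correlation). The Dlk1-Dio3 list (0.0423; adjusted p = 0.82 with an estimated correlation) and the hypertrophy and stress list (0.046; adjusted p = 0.56 with an estimated correlation) lay lower. The miR-30 and hypertrophy tests did not pass with lane as a covariate (adjusted p = 0.777 and 0.325), and with total count scaling the miR-30, Dlk1-Dio3 and hypertrophy tests had adjusted p between 0.0521 and 0.0554. Without sham P1 replicate 2 or MI P1 replicate 1 none of the 4 list tests passed, with adjusted p up to 0.276 for the erythroid list. The miR-30 test was also lost without sham P1 replicate 3 or MI P1 replicate 2 or 3, and the Dlk1-Dio3 and hypertrophy tests without any sham P7 library, the Dlk1-Dio3 test without MI P7 replicate 1 or 2, and the hypertrophy test without sham P1 replicate 3 or MI P1 replicate 2. No member of any other list passed, and adjusted over the list alone 1 of 12 miR-17/92 and 1 of 9 other-tissue miRNAs were lower. Median, mean and test did not share a sign in the miR-17/92 and let-7 lists.

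At 21 days after MI at P7 the fibroblast-associated miR-199a-5p rose from 333 ± 42.7 to 1423 ± 648 CPM (SD, n = 3 each), a log2 fold change of 2.10 ± 0.33 (SE, adjusted p = 0.0031), and miR-21a-5p, a promoter of cardiac fibrosis, from 5378 ± 487 to 15122 ± 8661 CPM (1.49 ± 0.32, adjusted p = 0.0084). The p53-inducible miR-34b-5p (chromosome 9, 51103562 to 51103645) rose from 6.68 ± 1.30 to 44.6 ± 25.1 CPM (2.73 ± 0.37, adjusted p = 0.0024). The striated muscle miRNA miR-133a-3p fell from 133590.0 ± 12292 to 66440.1 ± 18770.5 CPM (-1.01 ± 0.21, adjusted p = 0.0084) and miR-378a-3p, encoded within the metabolic coactivator gene Ppargc1b, from 74816 ± 9669 to 39304 ± 11545 CPM (-0.93 ± 0.21, adjusted p = 0.011).

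For MI at P7 at 21 days, 132 of 598 miRNAs passed, 79 higher and 53 lower, and 151 and 16 with total count scaling. The other named higher miRNAs were miR-21a-3p (2.16 ± 0.37), miR-34c-5p (2.10 ± 0.51), miR-214-5p (1.90), miR-214-3p (1.84), miR-146b-5p (1.80), miR-199a-3p and its near copy miR-199b-3p (1.66 each), miR-140-5p (1.60) and miR-140-3p (1.45). The other named lower ones were miR-486a-3p (-1.70), miR-486b-3p (-1.49), miR-215-5p (-1.32), miR-150-5p (-1.26), miR-128-3p and miR-30c-1-3p (-1.17 each), miR-133a-5p (-1.11), miR-181a-2-3p (-0.97), miR-30e-3p (-0.94) and miR-335-5p (-0.92). Of the 24 named calls 19 held in every fit with 1 library left out. miR-34c-5p missed the threshold without sham P7 replicate 1 or 2, miR-128-3p and miR-30c-1-3p without sham P7 replicate 2 or MI P7 replicate 1, and miR-30e-3p and miR-335-5p without sham P7 replicate 1 or MI P7 replicate 1, with adjusted p up to 0.0794. The count was 60 without MI P7 replicate 1, 65 without sham P7 replicate 2 and 73 without sham P7 replicate 1. It was 29 with only the 2 groups in the fit and 3 without both MI P7 replicates 1 and 3, which stand apart on the first component (13.7 and 15.2, against 2.47 for replicate 2).

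All 7 fibroblast-associated miRNAs rose 21 days after MI at P7, in the main test and adjusted over the list alone, including both arms of miR-214 (chromosome 1, 162223368 to 162223477, in an exon of Dnm3os) and miR-199b-5p (1.40), with a list adjusted p = 1.0e-08 (adjusted p = 0.37 with an estimated correlation). These members are not all separate evidence. Both arms of miR-21a, of miR-199a and of miR-214 are among them, and a miR-199a hairpin also lies in an exon of Dnm3os. Of 5 miR-34 miRNAs 4 rose, and 5 adjusted over the list alone (list adjusted p = 1.6e-04; adjusted p = 0.44 with an estimated correlation). The miR-34b and miR-34c hairpins are neighbours on chromosome 9 (51103562 to 51103645 and 51103034 to 51103110). Their arms are thus not separate evidence either. The Dlk1-Dio3 cluster rose in 23 of 51 members, and 28 adjusted over the list alone (list adjusted p = 3.8e-10; adjusted p = 0.40 with an estimated correlation). The 23 became 10 without MI P7 replicate 1, 11 and 15 without sham P7 replicates 2 and 1, and 33 with total count scaling. miR-127-3p went from 1871 ± 148 to 4281 ± 1592 CPM, and miR-136-3p rose by 0.89 and miR-381-3p by 0.92. Of 5 miR-30 members, abundant in cardiomyocytes, 4 fell in both adjustments (miR-30e-5p -0.77, miR-30d-5p -0.64), with list adjusted p = 0.0209 (adjusted p = 0.60 with an estimated correlation). The 4 became 2 with DESeq2 size factors and 0 with total count scaling, where the median log2 fold change was -0.30 in place of -0.64. They became 0 without any 1 sham P7 or MI P1 library, sham P1 replicate 3 or MI P7 replicate 1, 1 without sham P1 replicate 2 or MI P7 replicate 3, and 2 without sham P1 replicate 1. The list test did not pass without sham P7 replicate 1 or MI P7 replicate 1 (adjusted p up to 0.0935). Of 7 cardiac miRNAs 2 fell, miR-133a-3p and miR-133a-5p, while miR-1a-3p had -0.21 and miR-208a-3p -0.43 (list adjusted p = 0.046; adjusted p = 0.60 with an estimated correlation). The cardiac test had adjusted p = 0.0550 with lane, and did not pass with total count scaling or without sham P1 replicate 2, sham P7 replicate 1 or 2, or MI P7 replicate 1 or 2 (adjusted p up to 0.179). Without both MI P7 replicates 1 and 3, the median log2 fold change was 0.93 in place of 1.84 for the fibroblast-associated list. It was 1.38 in place of 2.26 for miR-34 and 0.65 in place of 0.68 for Dlk1-Dio3. For the cardiac list it was -0.46 in place of -0.32, and for miR-30 -0.19 in place of -0.64. This fit holds 1 MI P7 library, so its calls and list tests do not measure the spread between MI P7 samples and decide nothing for these lists.

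In lists whose test did not pass, 1 of 12 miR-17/92 members fell (miR-92a-3p -0.74), 1 of 3 miR-29 (miR-29c-3p -0.87), 1 of 4 mural (miR-145a-3p -0.54), 1 of 2 endothelial (miR-126a-3p -0.78, from 11161 ± 1195 to 6499 ± 2163 CPM) and 1 of 3 H19 and Igf2 hosted miRNAs (miR-483-3p -1.06). Of 9 immune miRNAs miR-146b-5p and miR-142a-3p (0.58) rose and miR-150-5p fell, and 1 of 10 hypertrophy and stress miRNAs rose, miR-221-3p (1.18). Among 9 other-tissue miRNAs the epithelial miR-200a-3p (1.91), miR-200b-3p (1.57) and miR-429-3p (1.55) rose from under 1 CPM to 2.62 ± 0.669, 2.96 ± 1.38 and 2.61 ± 1.89 CPM, and the neuronal miR-9-3p fell (-1.39). None of the miR-15, let-7, erythroid or hypoxia members passed. In the let-7 and mural lists the signs of median, mean and test differed. Adjusted over the list alone the counts differed for miR-29 (1 higher, 1 lower), immune (2 and 2), hypertrophy (2 and 1), other-tissue (3 and 2) and H19 and Igf2 hosted miRNAs (2 lower).

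**Figure D3:**
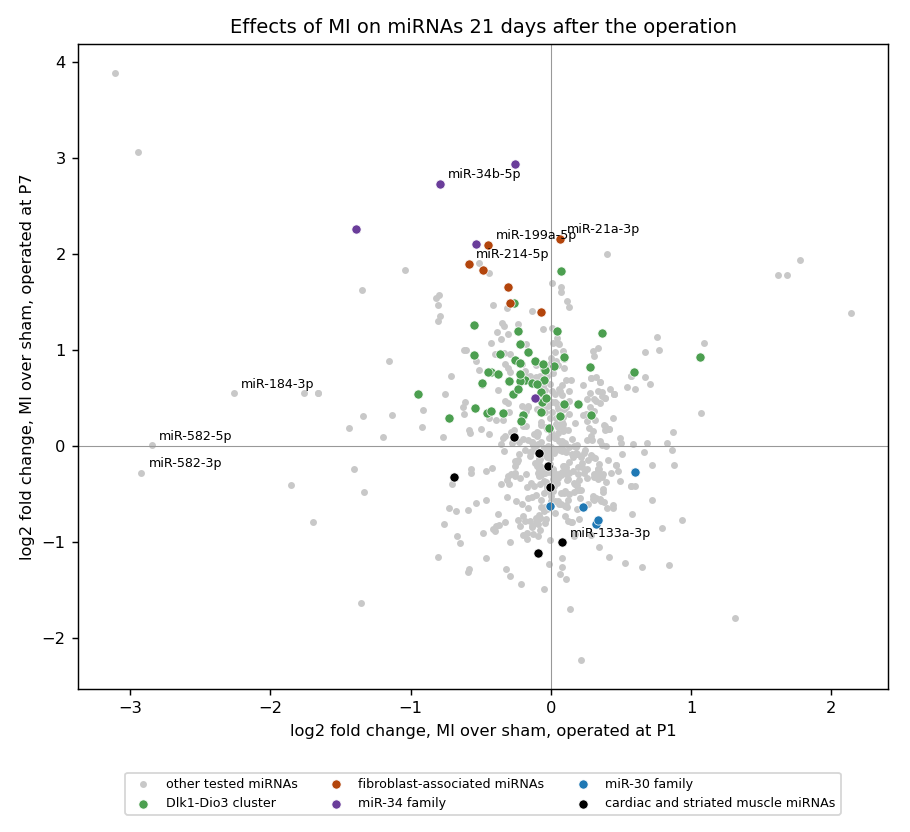
Log2 fold changes of MI over sham at 21 days for each tested miRNA, operated at P1 on the horizontal axis and at P7 on the vertical axis, with fixed lists coloured. All 7 fibroblast-associated miRNAs lie between 1.40 and 2.16 on the vertical axis, and miR-582-3p lies at -2.92 on the horizontal axis.

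Among the named miRNAs, the difference of the MI effects at 21 days, P7 minus P1, was largest for miR-34b-5p, at a log2 value of 3.52 ± 0.51 (SE, n = 3 per group, adjusted p = 0.0051), where MI at P1 gave -0.79 ± 0.36. miR-199a-5p differed by 2.54 ± 0.46 and miR-214-3p by 2.32 ± 0.45 (adjusted p = 0.0092 each), and miR-582-5p and miR-582-3p by 2.85 ± 0.53 and 2.64 ± 0.51, since they fell after MI at P1 and had 0.01 and -0.28 after MI at P7. miR-133a-3p differed by -1.09 ± 0.30 (adjusted p = 0.036) and miR-378a-3p by -1.21 ± 0.30 (adjusted p = 0.023). In all, 59 of 598 miRNAs passed, 47 higher and 12 lower, and 135 and 2 with total count scaling. Each group at 21 days has its own title code, so a difference between codes cannot be told from a difference of MI effects.

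With lane as a covariate 0 miRNAs passed for this difference, with 121 at an unadjusted p under 0.05. miR-34b-5p then had 3.26 (adjusted p = 0.0591) and miR-199a-5p 2.31 (adjusted p = 0.0595), all sham P1 libraries having been run in lane 3. Leaving out 1 library gave 16 calls without sham P1 replicate 2 or MI P1 replicate 1, 21 without MI P1 replicate 2, 25, 37 and 28 without sham P7 replicates 1, 2 and 3, 38 without sham P1 replicate 3, and 97 and 117 without MI P7 replicates 3 and 2. Of the 19 named differences 9 held in every such fit: miR-34b-5p, both arms of miR-582 and of miR-214, miR-199a-5p, miR-199a-3p, miR-199b-3p and miR-146b-5p. Such fits keep the same title code within each group, so they do not test a difference between codes. Members higher in this difference were 7 of 7 fibroblast-associated miRNAs (list adjusted p = 1.8e-08; adjusted p = 0.37 with an estimated correlation), 4 of 5 miR-34 miRNAs (3.1e-05; adjusted p = 0.40 with an estimated correlation) and 11 of 51 Dlk1-Dio3 miRNAs (3.8e-10; adjusted p = 0.40 with an estimated correlation). Adjusted over the list alone they were 7, 4 and 21. Arms of the same hairpin and neighbouring hairpins among these members are not separate evidence. The 11 Dlk1-Dio3 members became 35 with total count scaling and 5 without both MI P7 replicates 1 and 3. They became 0 and 7 without sham P1 replicates 2 and 3, 1 without MI P1 replicate 1 or 2, 3, 6 and 4 without sham P7 replicates 1, 2 and 3, and 6, 17 and 26 without MI P7 replicates 1, 2 and 3. Without sham P1 replicate 2 or MI P1 replicate 1 or 2 the fibroblast-associated members were 4 and the miR-34 members 2. The miR-30 list lay lower with 0 of 5 past and 4 adjusted over the list alone (0.0038; adjusted p = 0.56 with an estimated correlation). These 4 list tests also passed with lane as a covariate, with 0 members past (adjusted p = 5.0e-07, 1.1e-04, 1.7e-13 and 0.0088). In lists whose test did not pass, 1 of 7 cardiac, 1 of 4 mural (miR-145a-3p -0.87) and 1 of 3 H19 and Igf2 hosted miRNAs (miR-483-3p -1.41) were lower, and 1 of 9 immune and 1 of 10 hypertrophy and stress miRNAs (miR-221-3p 1.57) higher. Of 9 other-tissue miRNAs 3 were higher, miR-200a-3p (2.42), miR-200b-3p (2.37) and miR-429-3p (2.36), and 1 lower, miR-9-5p (-1.65). Adjusted over the list alone the counts differed for cardiac (2 lower), immune (1 higher, 2 lower), hypertrophy (3 higher) and other-tissue miRNAs (4 higher, 2 lower). The median, mean and test of the miR-17/92, let-7, miR-29 and immune lists differed in sign.

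**Figure D4:**
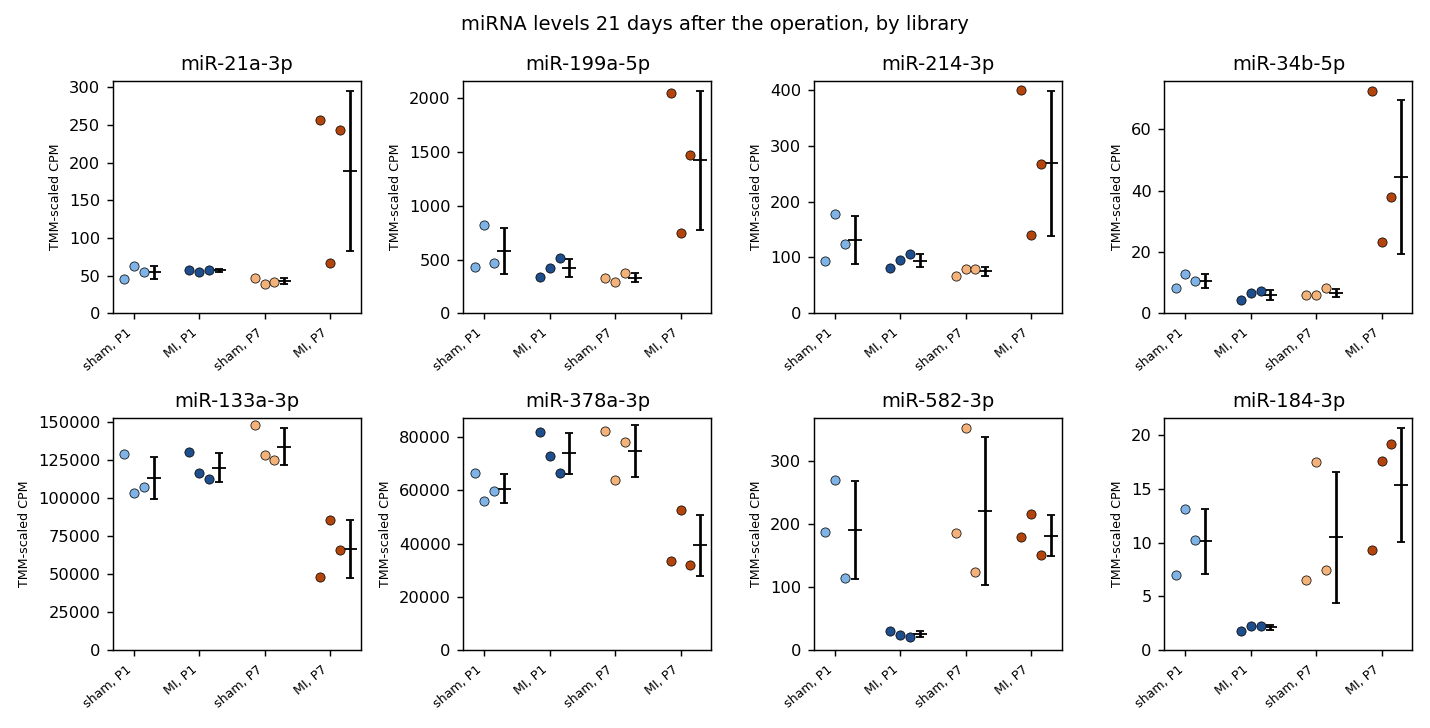
TMM-scaled CPM of single miRNAs in the 21-day libraries, with 1 point per library and bars for the mean and SD of each group (n = 3). miR-582-3p was at 25.3 ± 5.06 CPM in MI P1 against 191 ± 78.2 CPM in sham P1, and miR-34b-5p at 44.6 ± 25.1 CPM in MI P7 against 6.68 ± 1.30 CPM in sham P7.

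Between sham hearts of 22 and 28 days of age 0 of 598 miRNAs passed in edgeR, with 72 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0957, while limma-voom called 0, DESeq2 14 and edgeR with no filter 29. The 6 smallest p, none past the threshold, belonged to miR-708-5p (-0.97), miR-200a-3p (-1.37), miR-342-3p (1.44 ± 0.34, 58.9 ± 23.6 and 160.1 ± 33.2 CPM), miR-708-3p (-0.90), miR-298-5p (-2.07 ± 0.47) and miR-205-5p (-1.82). The antifibrotic miR-29 list lay higher (adjusted p = 3.4e-04; adjusted p = 0.19 with an estimated correlation), with 0 of 3 past and 3 adjusted over the list alone, miR-29a-3p, miR-29b-3p and miR-29c-3p having 0.70, 0.70 and 0.71. The Dlk1-Dio3 list (adjusted p = 3.5e-08; adjusted p = 0.52 with an estimated correlation) and the fibroblast-associated list (0.0116; adjusted p = 0.60 with an estimated correlation) lay lower and the miR-30 list higher (0.0209; adjusted p = 0.60 with an estimated correlation), with 0 members past either adjustment. Other-tissue miRNAs lay lower (0.0238; adjusted p = 0.37 with an estimated correlation), with 0 of 9 past and 5 adjusted over the list alone. With lane as a covariate the fibroblast-associated and miR-30 tests did not pass (adjusted p = 0.0625 and 0.108), and with total count scaling the other-tissue test did not. The fibroblast-associated test was lost without sham P1 replicate 2 (adjusted p = 0.141), the miR-30 test without sham P1 replicate 2 or 3 or sham P7 replicate 1 (adjusted p up to 0.107), and the other-tissue test without sham P1 replicate 1 or sham P7 replicate 2 (adjusted p up to 0.146). No member of any other list passed, and adjusted over the list alone 1 cardiac and 1 H19 and Igf2 hosted miRNA were lower and 1 immune miRNA higher.

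Across miRNAs, which are not independent replicates, the log2 fold changes of MI at P1 and at P7 had Pearson and Spearman correlations of 0.50 and 0.49 at 3 days (446 miRNAs) and of -0.17 and -0.13 at 21 days (598). At 3 days, 5 miRNAs were higher in both, miR-134-5p, miR-146b-5p, miR-206-3p, miR-34c-5p and miR-494-3p, where 0.309 would be shared by independent lists. The P1 values at 3 days use both kinds of sham P1 library. Without the code 1103 libraries 0 miRNAs passed for MI at P1, so 0 calls would be shared. The correlations were not recomputed without them. For MI at P7, the 2 follow-ups had correlations of 0.50 and 0.57 over 404 miRNAs, with 8 shared higher calls against 2.96 by chance and 1 shared lower call, miR-181c-3p, against 0.193. The shared higher calls were miR-134-5p, miR-146b-5p, miR-214-5p, miR-21a-3p, miR-341-3p, miR-34c-5p, miR-381-3p and miR-666-3p. For MI at P1 the follow-ups had -0.16 and -0.18 with 0 shared calls, and for sham age 0.09 and 0.15. Of the 132 miRNAs past the threshold for MI at P7 at 21 days, 56 had the same sign after MI at P1.

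The share of counts taken by the 10 leading miRNAs of a library fell after MI at 3 days, from 68.6 ± 8.45% to 57.6 ± 0.777% at P1 and from 78.6 ± 1.29% to 73.9 ± 1.67% at P7 (SD, n = 4 each; p = 0.0286 each, the smallest an exact two-sided permutation test allows here). Sham P7 lay 10.1 percentage points above sham P1 (exact permutation p = 0.0286). The sham P1 shares were 60.7% and 61.8% in the code 1078 libraries and 76.5% and 75.2% in the code 1103 libraries, so both P1 comparisons at 3 days depend on the code. At 21 days the shares were 63.4 ± 0.771% in sham P1, 65.7 ± 0.759% in MI P1, 66.5 ± 1.57% in sham P7 and 59.9 ± 2.60% in MI P7 (n = 3 each). Each of those 3 comparisons had p = 0.1, the smallest the exact permutation test allows with 3 against 3, so this design cannot pass the threshold.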

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

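In this part the test of a lower share of cardiomyocytes, the GC correction, the match of calls before and after thinning and the fits without code 1103 or 1078 and without MI P7 replicates 1 and 3 were chosen after the result was seen. Of 144 groups of 4 libraries examined for a value far from the other 3, 5 held one, and chance gives about 1 in 20. miR-142a-3p was at 686 CPM in MI P1 replicate 2 at 3 days, against 117 to 213 CPM in the others of its group. miR-146b-5p was at 71.6 CPM in MI P7 replicate 1, against 103 to 109 CPM. miR-195a-3p was at 56.9 CPM in sham P1 replicate 3, against 36.1 to 39.6 CPM. miR-215-5p was at 24.0 CPM in sham P7 replicate 4, against 6.29 to 8.78 CPM, and miR-10b-5p at 3.29 CPM in sham P7 replicate 3, against 11.02 to 12.6 CPM.

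The effects of MI at P7 and P1 differed at 21 days, by a test of the difference itself, for 59 miRNAs. Each group at 21 days has its own title code. A difference between codes thus cannot be told from a difference of MI effects, and the p-values measure only the spread within a code. The named log2 differences were 3.52 for miR-34b-5p, 2.85 for miR-582-5p, 2.64 for miR-34c-5p and for miR-582-3p, 2.54 for miR-199a-5p, 2.48 for miR-214-5p, 2.32 for miR-214-3p, 2.24 for miR-146b-5p, 2.09 for miR-21a-3p, 1.97 for miR-199b-3p and miR-199a-3p and 1.79 for miR-21a-5p. On the lower side they were -1.65 for miR-9-5p, -1.21 for miR-378a-3p, -1.10 for miR-30e-3p, -1.09 for miR-133a-3p, -0.96 for miR-30d-3p, -0.95 for miR-378c and -0.87 for miR-145a-3p. With lane as a covariate 0 miRNAs passed for this difference. The list medians of the log2 difference were then 2.78 in place of 3.19 for miR-34 and 1.72 in place of 2.09 for fibroblast-associated miRNAs. They were 0.96 in place of 0.83 for Dlk1-Dio3 and -0.71 in place of -0.87 for miR-30.

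Other splits of the same libraries show where a count is unlikely by chance. For MI at P7 at 3 days the real split gave 25 calls and the highest other of 35 splits 0, so chance alone is unlikely if libraries are exchangeable. The smallest share these splits allow is 1 of 35, not adjusted over comparisons. Mixed splits also put any real difference into the spread within groups, which can lower their counts. Title codes are nested in these groups, with all sham P7 libraries in code 1075, and with the title code as a random block 0 miRNAs passed in limma-voom (12 at an unadjusted p under 0.05), so a difference between codes is not excluded. For MI at P1 at 3 days (82 calls; 3 of 35 splits as large, highest other 104) and for sham age at 3 days (98; 6 of 35, highest other 222) chance is not excluded. The split with 222 put the code 1078 libraries with sham P7 replicates 1 and 4. For the difference at 3 days the real count is 0, so all 100 of 100 splits are as large (highest other 79) and the count of splits decides nothing. For the difference at 21 days 2 of 100 splits were as large as the real 59, the highest other giving 71. The 10 splits at 21 days are too few for MI at P1 (3 calls, 1 split as large, highest other 0), MI at P7 (132, 1, 0) and sham age (0, 10, 0).

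At 3 days the code 1103 and code 1078 libraries of sham P1 differed in 350 of 480 miRNAs, 164 higher and 186 lower in code 1103. A loss of GC-poor miRNAs fits: across 427 miRNAs (95.7% of those tested), which are not independent replicates, the log2 ratio of code 1103 to 1078 had a Spearman rho of 0.517 with GC content, and medians of -1.85 up to 46.3% GC and 1.51 from 55.0% GC. With a GC correction MI at P1 had 68 calls, 44 of them among the 82, and sham age 103, 85 of them among the 98. The GC content is that of the hairpin arm and not of the mature miRNA. Calls left after this correction therefore do not exclude a loss of GC-poor miRNAs as their cause. After thinning the code 1078 libraries to 1.41 M counts 314 calls were made, 0.897 of the number before. Thinning keeps the proportions within a library, so it tests only the sampling of fewer reads, which does not account for most of the calls. Whatever left the code 1103 libraries with fewer reads was not tested. Thinning was not applied to sham P7 against sham P1. Of the 350, 298 were still tested and 288 were called again in the same direction, and 26 of the 314 had not been called before. Whether the sham age calls are the same library difference rather than age stays open: 25.5% of the 98 (25) stayed with code 1103 alone, 79 of 98 kept their sign and the median size went from 1.92 to 0.928. Spearman rho of fold change with GC was -0.456 for MI at P1, -0.119 for MI at P7 and 0.371 for sham age at 3 days, and 0.00584, -0.120 and 0.0533 at 21 days.

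At 21 days miR-582-3p, miR-582-5p and miR-184-3p were lower after MI at P1. Lane is excluded as the whole cause for miR-582-3p, which had -2.84 with lane as a covariate (adjusted p = 0.0167), with miR-582-5p at -2.66 (adjusted p = 0.0250) and miR-184-3p at -2.19 (adjusted p = 0.142). All MI P1 libraries at 21 days share title code ICR405 and no other group has it, so a difference carried by those mice, for instance a variant of this outbred stock, may be the cause and cannot be told from infarction. At 3 days the summed miR-582 level in MI P1 was 13.0 ± 2.80 CPM, 1.21 times the 10.7 CPM of the code 1078 sham libraries.

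At 21 days 7 of 7 fibroblast-associated, 4 of 5 miR-34 and 23 of 51 Dlk1-Dio3 miRNAs were called higher after MI at P7. Members that share a hairpin or a locus are not separate evidence. For the fibroblast-associated list, the values argue against a lower share of cardiomyocytes, with all other cell types alike, as the whole cause. The endothelial median lay 2.42 log2 units under the fibroblast-associated one (a difference of -2.42, mural -1.80). The highest of 6 endothelial and mural members had 0.84 against a lowest fibroblast-associated 1.40. The miR-34 and Dlk1-Dio3 lists were not part of this test. The Dlk1-Dio3 median of 0.68 lies under 0.84, so that list does not stand apart in this way. Whether 2 of the 3 MI libraries carry the change stays open. In replicate 2 all 34 called members (100%) lay above every sham P7 library, but they were called in a fit that holds replicate 2, so this decides nothing. With replicate 2 as the only MI P7 library, the median log2 fold change was 0.93 in place of 1.84 for the fibroblast-associated list. It was 1.38 in place of 2.26 for miR-34 and 0.65 in place of 0.68 for Dlk1-Dio3. The Dlk1-Dio3 median thus stayed about as large and the other medians were smaller, but 1 library decides nothing. In the fit of all libraries the 3 camera list tests had adjusted p = 0.37, 0.44 and 0.40 with an estimated correlation. Title code coincides with group at 21 days and stays open too, so the pattern is not assigned to infarction.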

How the results depend on the processing

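The fits without code 1103 or 1078, without MI P7 replicates 1 and 3, from deposited hairpins and with GC correction, and the list test settings other than fry and the estimated correlation, were chosen after the first results. Of 2172 recomputed values of named miRNAs 1531 were the same, 608 lost their call, 26 gained one and 7 reversed. Calls follow as MI at P1, MI at P7, difference and sham age where they moved; the cause was not tested beyond fewer libraries or miRNAs. At 3 days they were 16 for P7 with DESeq2 size factors; 32 for P1 and 58 for P7 with total count; 15 for P1 and 8 for P7 with no filter; 45 for sham age with the stricter filter. DESeq2 gave 52 for P7 and 6 for the difference, limma-voom 11 for P1 and 62 for sham age. Fits of 2 groups gave 0, 65 and 0 for P1, P7 and sham age, the title code as a random block 0, 0 and 0, and hairpins 124 for P1. Without code 1103 they were 0, 93, 1 and 352. Sham age without code 1078 reversed miR-301a-5p (1.08), let-7c-1-3p (0.87), miR-15b-3p (1.32), miR-215-5p (0.51), miR-10b-5p (1.32), miR-98-5p (1.62) and miR-379-5p (0.55).

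At 21 days total count gave 137 for the difference and 2 for sham age, no filter 12 for P1, 96 for the difference and 29 for sham age, and the stricter filter 81 for P7 and 38 for the difference. DESeq2 gave 91 for the difference and 14 for sham age, fits of 2 groups 5, 29 and 22 for P1, P7 and sham age, and lane 0 for the difference. Without MI P7 replicates 1 and 3 there were 3 for P7 and 26 for the difference. A replicate block gave 1 for P1, 62 for P7, 3 for the difference and 0 for sham age. Deviations of libraries with the same number had correlations of -0.00 and -0.06 at P1 and -0.07, 0.10 and -0.06 at P7. Pairs with different numbers ranged from -0.13 to 0.18. So few pairs cannot tell whether the numbers pair the libraries. List tests passed 0 times at either follow-up with an estimated correlation, 17 times without code 1103 at 3 days and 9 times with fry at 21 days. The share of the leading miRNA differed by -7.89 (exact two-sided permutation p = 0.0571) for P1, 2.93 (p = 0.143) for P7 and 0.684 (p = 0.914) for sham age at 3 days, and by -0.370 (p = 0.4) for P1 at 21 days.

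Leaving out 1 library gave, at 3 days, 0 to 164 calls for P1, 13 to 23 for P7, 0 to 0 for the difference, 17 to 185 for sham age and 10 to 12 list tests. At 21 days it gave 2 to 3, 60 to 190, 16 to 117, 0 to 0 and 11 (without sham P1 replicate 2) to 22 (without MI P7 replicate 3). Simulation with the real depths and dispersions recovered 29.6% of 4-fold changes for the difference at 3 days; it does not set depth apart from dispersion.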

Other observations

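The miRNAs in this part were chosen after their values were seen. Besides miR-378a-3p, other members of the miR-378 family, linked to mitochondrial metabolism, fell 21 days after MI at P7 (n = 3 each): miR-378c by 0.80 ± 0.20 (SE, adjusted p = 0.015), miR-378b by 0.68 ± 0.20 (adjusted p = 0.031) and the scarce miR-378d by 1.24 ± 0.33 (adjusted p = 0.018). These share much of their sequence, so reads may be shared, and the members are not separate evidence. Without MI P7 replicates 1 and 3, 3 miRNAs passed in this comparison. miR-181a-2-3p, miR-181a-1-3p and miR-181c-3p, from clusters known in lymphocytes and muscle, fell by 0.97, 0.83 and 0.83. miR-194-5p fell from 272 ± 13.5 to 157 ± 54.2 CPM, beside miR-215-5p, which shares a genomic cluster with a miR-194 copy.

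Several miRNAs outside the fixed lists rose in the same comparison. miR-218-5p, hosted by the Slit genes, rose from 38.6 ± 9.83 to 89.98 ± 15.5 CPM (1.22 ± 0.21, adjusted p = 0.0031), and miR-455-5p, hosted by a collagen gene, from 43.1 ± 6.004 to 104 ± 25.8 CPM (1.27 ± 0.22, adjusted p = 0.0031). miR-152-3p rose by 1.25 ± 0.29 and miR-574-3p by 1.07 ± 0.22. The sensory epithelium miRNAs miR-182-5p and miR-183-5p rose by 1.00 ± 0.27 and 1.30 ± 0.41, the latter from 1.82 ± 0.399 to 4.45 ± 2.24 CPM. The difference from MI at P1 was 1.61 for miR-182-5p (adjusted p = 0.020) and 2.10 for miR-183-5p (adjusted p = 0.036), and with lane as a covariate 0 miRNAs passed for this difference in edgeR (121 at an unadjusted p under 0.05).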
